A study of Mus musculus with 4 samples.

How the data were processed

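The series holds 4 two-colour microarrays of mouse lung RNA, and each compares amplified RNA of 1 bleomycin-treated A/J mouse with the same pool of amplified RNA from control A/J lungs, per the labels. The arrays form 1 group of 4 treated mice. Per the labels, the mice are numbered 1 to 4, and each was taken as 1 replicate. The pool counts as 1 control sample, so that the test of the ratio against 0 is the comparison between treatment and control and leaves out the spread between control mice.

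The authors deposited 1 value per spot and array, a log ratio of the 2 channels that was read here as log2. Scanner, dyes, background correction and normalization are not given in the sources used here. The base was inferred from the values: the lowest was -6.1, which as log10 would mean a ratio beyond any plausible range for most arrays, and the natural logarithm could not be ruled out. With the natural logarithm, all sizes on the log2 scale would grow by 1 common factor, the tests against 0 would not change, and the counts of genes over a fold size would. The direction of the ratio stays unknown, and no dye swap is recorded. Array medians before centring were -0.009, 0.015, 0.029 and 0.019, and standard deviations over spots were 0.449, 0.439, 0.486 and 0.351. Of 17280 spots, 6911 had a value on all 4 arrays, 2998 on 3, 2297 on 2, 1986 on 1 and 3088 on 0, and the first 420 spots of the table had none. Which spots the authors left empty, and by what rule, is not given. Signal and background are not part of the table used here, so dim spots could not be judged. No other column of per-sample values was in the table (0 columns).

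Probes were named through a table of the platform's annotation, which can be old. It listed 14723 of the spots, 14722 with 1 gene symbol and 1 with several, and 2557 spots were not listed and are unnamed here. Gene IDs of 14445 probes were matched to a RefSeq gene table of the assembly GRCm38.p6, which changed 0 symbols. That table was also used for the genomic span of genes, and no coordinates are reported. The named probes covered 13410 genes. The 1000 spots with at least 3 values and no single symbol were tested as probes only.

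Each array was centred on its median. A spot or gene needed a value on at least 3 of the 4 arrays, which left 9909 probes and 8384 genes (6057 with 4 values and 2327 with 3). For genes, the values of all probes with the same single symbol were averaged on each array. Of 409 genes with several such probes, 221 had probe means on both sides of 0, but among the 43 that passed the test only 5 did: Ankib1, Ep400, Tenm2, Cgrrf1 and Dnaja3. The mean log ratio was tested against 0 with limma (version 3.58.1, R 4.3.3), by lmFit with an intercept and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes or all probes tested and a threshold of 0.05. Errors are standard deviations between mice. Genes with over 2-fold difference on every array were counted without a test.

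The 33 gene lists, 17 of pathways and 16 of cell type markers, were fixed before the data were examined. The count of members that passed is given over all genes tested and also adjusted over the list alone. Each list with at least 5 genes was tested with limma's camera against all other genes with 4 values, with the preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Alternatives were an estimated correlation, limma's fry, which does not compare a list with other genes, and cameraPR on all genes with at least 3 values, so that this one changes both the test and the genes. Without a mouse, camera took the genes with a value on all 3 other arrays, which added genes to some lists. The 6 lists that passed camera were the respiratory chain, cardiac and skeletal muscle, ribosomal proteins, endothelial cells, protein folding and the cell cycle. With an estimated correlation 0 lists passed, but this setting rests on the few degrees of freedom of 4 arrays, so hardly any list could pass. Estimated correlations as unlike as 0.269 (respiratory chain) and 0.0247 (protein folding) both came with a camera adjusted p of 0.602. The adjustment gave this value to several lists at once, so the match says nothing about the correlations. A loss in this setting shows neither that correlation between genes undid a call nor that it did not. The estimates for the respiratory chain, muscle (0.437) and the cell cycle (0.378) lay far above the preset 0.01. The camera p values of these 3 lists depend on that preset and may be too small.

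The rule for named genes was fixed before the data were examined. It takes the 12 genes farthest above and the 12 farthest below 0 among those past the test with the same sign on every array. It adds up to 4 members with the smallest p of each list that passed or that had a member past the test. It also takes 35 genes of lung injury and lung cells whatever their value. Of these 35, 18 were tested; of the other 17, 8 had a probe with too few values (Col1a2, Timp1, Ccl2, Saa3, Arg1, Mmp12, Acta2 and Top2a) and 9 had no probe named for them. Genes outside the rule are said to be chosen after their values were seen.

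The procedure was tested on simulated data with the real genes, spreads and missing values. In 5 runs, 200 of the 8384 genes were shifted by known amounts. Of genes shifted by 0.5, 1 and 2 on the log scale, 39.4%, 82.1% and 94.2% were recovered, with 0 wrong signs, and 33 unshifted genes were called in all runs together. The shifted list was called in 5 of 5 runs, and 0 of 150 unshifted lists were. The simulated errors were independent between genes and between arrays, and the simulated lists were random sets of genes. Error of the shared pool and the resemblance of the arrays of mice 1 and 2, and of mice 3 and 4, were therefore not covered. Neither was correlation within lists, estimated at -0.146 (mast cell and eosinophil) to 0.592 (ciliated cell) in the real lists. The numbers of unshifted genes and lists called are thus no false-call rates for the real data.

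The counts of genes and probes past the test were recomputed without centring, with equal spread on every array, with values required on all 4 or at least 2 arrays, with a robust variance prior, with array weights and without each mouse in turn. Further alternatives for them were an adjusted p of 0.01, a 1.5-fold minimum and, for genes, 1 probe per gene. The count over 2-fold was repeated without centring, with equal spread, without each mouse and at 1.5-fold, and the count of lists, beside the other tests named above, without centring and without each mouse. Removal of a trend with genomic span (lowess, span 0.3) and removal of muscle and fat genes were added after seeing the data. So were 2 settings for the arrays that resembled each other, of mice 1 and 2 and of mice 3 and 4: the pairs as a random block (limma's duplicateCorrelation, consensus correlation 0.304 over genes) and 1 mean per pair. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.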

Results

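Gene expression was measured in the lungs of 4 bleomycin-treated A/J mice, each on its own 2-colour array against the same pool of amplified RNA from the lungs of control A/J mice. Bleomycin is a DNA-damaging drug that is used to injure the lung in animals, and A/J is an inbred strain of laboratory mouse. The comparison asks which genes differ between treated and control lungs. Dose, route and time after treatment are not given in the sources used here. The table held 17280 spots, of which 12136, 11373, 9427 and 10282 had a value for mice 1, 2, 3 and 4. A value was a log ratio between the treated mouse and the pool, with medians of -0.009, 0.015, 0.029 and 0.019 before centring. The number of arrays limits the precision. All p-values rest on the spread between the 4 mice and leave out the spread between control mice, since there was 1 pool.

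Neither the labels nor the table say which of the 2 RNAs is on top of the ratio. By the order of the titles alone, the treated mouse would be the numerator, and values above 0 would then be higher in treated lungs. This is not settled. The matrix, p53 target and macrophage lists, fixed beforehand to be set beside the direction, had 7 members past the test above 0 and 7 below. Matrix genes had 4 above and 3 below, p53 targets 1 above and 3 below, and macrophage genes 2 above and 1 below. Genes and groups are therefore given by their side of 0, and every value would change sign, with its size and p kept, if the pool were on top. The base of the logarithm is not stated either. It was taken as 2, and fold sizes and counts of genes over a fold size hold only under that reading.

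Among the genes that passed the test, Hspa1a, Pabpc1 and Fmo2 lay farthest above 0, and Tnnc2, Myl1 and Cidea farthest below it. Of 8384 genes tested, 1048 passed (limma, Benjamini-Hochberg adjusted p at most 0.05), 645 above and 403 below 0. All 1048 had the same sign on every array with a value, and 2664 genes had an unadjusted p under 0.05. At the level of probes, 1273 of 9909 passed, 802 above and 471 below 0. On all 4 arrays, 32 of 6057 genes exceeded a 2-fold difference, 26 above and 6 below 0. The 2-fold count was 43, 58, 41 and 50 without mouse 1, 2, 3 or 4, when only the 3 remaining arrays had to exceed it. With 3 mice the test passed fewer genes: 317 without mouse 1, 573 without mouse 2, 296 without mouse 3 and 333 without mouse 4, and 187 of the 1048 passed in each of these 4 fits. The probe counts in those fits were 472, 662, 448 and 521. These p-values treat the 4 arrays as independent, although those of mice 1 and 2, and of mice 3 and 4, resembled each other. With these pairs as a random block, a setting chosen after seeing the data, 402 genes passed limma (286 above and 116 below 0), all among the 1048, and 565 probes. Over 1 mean per pair, thus 2 values, 0 genes and 0 probes passed limma, with 1566 genes and 1874 probes at an unadjusted p under 0.05.

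Above 0, the stress-inducible chaperone gene Hspa1a had the largest mean log ratio, 2.61 ± 0.66 (SD, n = 4), a 6.12-fold difference. Its value averages the probes present on each array, which can differ between mice. The 13 Hspa1a probes with at least 3 values had means with a median of 2.95. Pabpc1, which encodes a poly(A)-binding protein, followed at 1.90 ± 0.61 (SD, n = 4). The monooxygenase genes Fmo2 and Fmo1 had means of 1.81 ± 0.11 and 1.69 ± 0.68 (SD, n = 4), and Fmo2 had the smallest limma adjusted p of all genes, 0.00308. Inmt, a methyltransferase gene of lung, had a mean of 1.78 ± 0.45 (SD, n = 4). Tmem100, an endothelial gene, and Ormdl2, a regulator of sphingolipid synthesis, both had means of 1.61. The remaining genes of the 12 were Hsph1 at 1.63, Hsp90aa1 at 1.52, 3021401C12Rik with values from 1.35 to 1.64, Cacybp at 1.46 and Hsd3b7 at 1.45. Of these 12, Hsph1 no longer passed whichever mouse was left out and Fmo1 without mouse 4, at limma adjusted p up to 0.0905.

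Below 0, Tnnc2, the fast skeletal muscle troponin C gene, had the largest mean, -4.90 ± 0.64 (SD, n = 3), followed by the fast myosin light chain gene Myl1 at -2.91 ± 0.65 (SD, n = 4). Cidea, a lipid droplet gene of brown fat, had a mean of -2.53 ± 1.55 (SD, n = 4). S100a8 and S100a9, which encode the subunits of calprotectin and are abundant in neutrophils, had means of -2.28 ± 0.62 and -2.08 ± 0.72 (SD, n = 4). The muscle genes Hrc, Cox7a1, Cox8b and Ldb3 lay at -2.17, -2.16, -2.15 and -1.67, and Nppb, a natriuretic peptide gene of the heart, at -2.12. Mt2, a metallothionein gene, and Reg3g, an antimicrobial lectin gene, had means of -1.81 and -1.75. Of these 12, Tnnc2, Myl1, S100a8 and Reg3g passed limma whichever mouse was left out. Cidea, Hrc, Cox7a1, Cox8b, Nppb and Mt2 were lost without mouse 1, 3 or 4, Ldb3 without mouse 3 or 4 and S100a9 without mouse 4, at adjusted p up to 0.131. Mt2 has no value in mouse 1, so its loss there reflects the changed fit and adjustment over the other genes and not its own values.

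**Figure D1:**
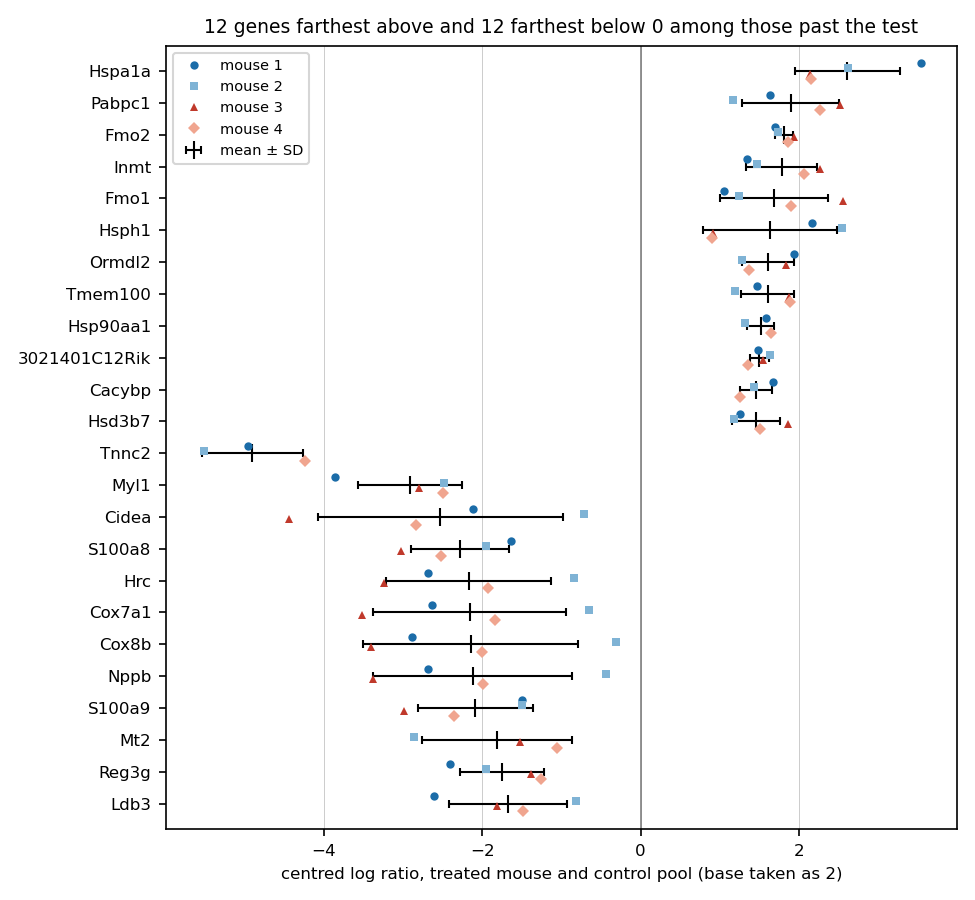
Centred log ratio between each treated mouse and the control pool (horizontal axis, base taken as 2) for the 12 genes farthest above and the 12 farthest below 0 among those that passed the test. Symbols are single mice and bars are the mean ± SD. Fmo2 runs from 1.70 to 1.94, while Cox8b runs from -0.31 in mouse 2 to -3.40 in mouse 3.

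The list with the smallest camera p was that of the mitochondrial respiratory chain. Of 65 tested members, 30 passed below 0 and 1 above, or 41 and 2 when adjusted over the list alone, and the median log ratio was -0.59. Atp5k and Atp5g2, which encode subunits of ATP synthase, had means of -1.61 ± 0.31 and -0.75 ± 0.11 (SD, n = 4). Cox6c and Cox5b, subunits of cytochrome c oxidase, had means of -1.50 ± 0.34 (SD, n = 4) and -1.06 ± 0.21 (SD, n = 3). The member above 0 was Ndufaf7, at 0.52, an assembly factor of complex I that was named after its value was seen. The list median was below 0 in all 4 mice, at -0.68, -0.43, -0.72 and -0.31. Against all other genes the list passed camera (adjusted p = 2.64e-10). This was lost at adjusted p = 0.602 with an estimated correlation, a setting in which hardly any list could pass with 4 arrays. The correlation within the list was estimated at 0.269, far above the preset 0.01 on which the camera p rests. By fry, which called 9 of the 33 lists, the respiratory chain list did not pass either (adjusted p = 0.0506). Muscle and brown fat are rich in mitochondria, and 5 of 23 muscle genes and 4 of 14 fat cell genes passed limma below 0. Without genes of these 2 lists, in 63 of the 65 genes, the median was -0.58. So few genes were dropped that this says little about such tissue. The 6 large subunits tested, a split made after some values of the list were seen, had a median of -0.14 and the other 59 members of -0.62. Of the genes named here, Cox5b was lost without mouse 1 (limma adjusted p = 0.0524).

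Of 53 tested ribosomal protein genes, 9 passed below 0 and 0 above, 12 and 1 when adjusted over the list alone, with a median of -0.19. Rpl39 had a mean of -1.06 ± 0.25, Rps26 of -0.69 ± 0.23 and Rps15 of -0.64 ± 0.14 (SD, n = 4), and Rpl38 of -0.73 ± 0.22 (SD, n = 3). The list passed camera (adjusted p = 0.00219), but not with an estimated correlation (adjusted p = 0.602) or by fry (adjusted p = 0.0506). Rps26 and Rpl38 were lost without mouse 1 or 3 and Rpl38 also without mouse 2, at limma adjusted p up to 0.0760.

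Some markers of striated muscle and of fat, tissues that can be taken out with a lung, differed between the mice, while others did not come near 0. If the treated mouse is on top of the ratio, such tissue in the 1 shared pool cannot be told apart from a difference common to the treated mice. If the pool is on top, values below 0 would instead mean more of these transcripts in the treated samples. In either case, the shared pool by itself would not make the mice differ from each other. Of 23 tested genes of cardiac and skeletal muscle, 5 passed below 0 and 0 above, 7 and 0 when adjusted over the list alone. The list median was -1.79 in mouse 1, -0.08 in mouse 2, -0.30 in mouse 3 and -0.63 in mouse 4. Camera gave an adjusted p of 0.000433, which became adjusted p = 0.709 with an estimated correlation, and fry gave an adjusted p of 0.128. Tnnc2 and Myl1 were far below 0 on each array with a value, the weakest being -4.24 and -2.49. Cox7a1, Cox8b and Nppb were closest to 0 in mouse 2, at -0.65, -0.31 and -0.43, and between -1.84 and -3.52 in the other mice. Myh6, the cardiac myosin heavy chain gene, did not pass (-0.17 ± 1.14, SD, n = 4; limma adjusted p = 0.807), with -1.64 in mouse 1 and 0.97 in mouse 2. Of 14 tested genes of fat cells, 4 passed below 0 and 0 above, 5 and 1 when adjusted over the list alone. These were Cidea, Adipoq at -1.59 ± 0.99 (SD, n = 4), Plin4 at -0.79 ± 0.29 (SD, n = 3) and Gpd1 at -0.54 ± 0.21 (SD, n = 4). The fat cell list did not pass camera (adjusted p = 0.296), but did so without mouse 2 (adjusted p = 0.00571). Of the 9 muscle and fat genes named as past the test, all but Tnnc2 and Myl1 were lost without mouse 1, 3 or 4, at limma adjusted p up to 0.132.

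**Figure D2:**
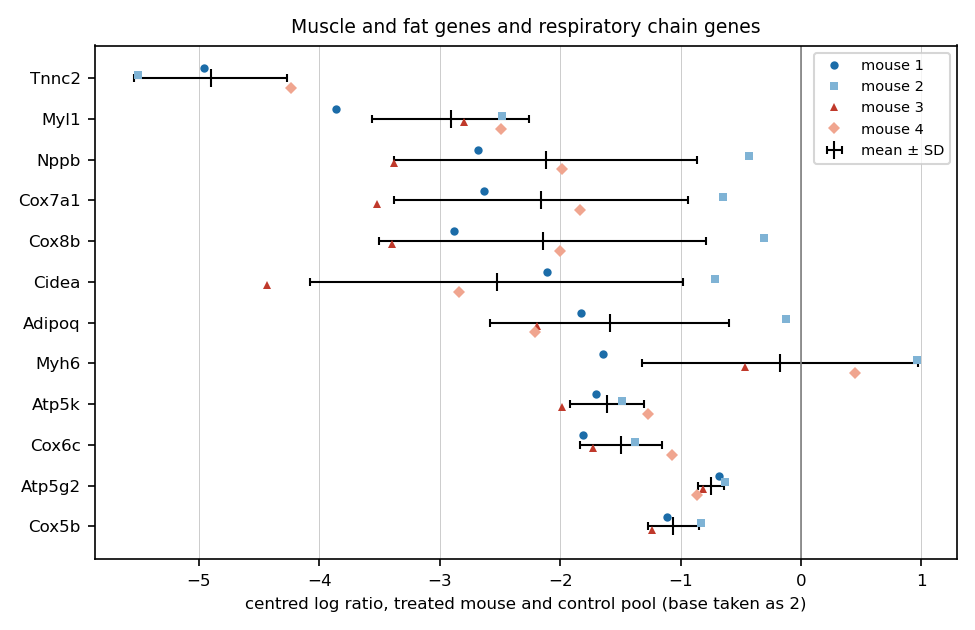
Centred log ratio (horizontal axis, base taken as 2) of muscle and fat genes and of respiratory chain genes in each treated mouse, with the mean ± SD as bars. Nppb, Cox7a1, Cox8b, Cidea and Adipoq lie between -0.12 and -0.72 in mouse 2, and Atp5k lies between -1.27 and -1.99 over the 4 mice.

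Of 30 tested genes of protein folding and endoplasmic reticulum stress, 10 passed above and 1 below 0, 19 and 1 when adjusted over the list alone, and the median was 0.34. Beside Hspa1a, the cytosolic chaperone genes Hsp90aa1 and Hspa8 had means of 1.52 ± 0.17 (SD, n = 3) and 0.93 ± 0.15 (SD, n = 4). Herpud1, which acts in the degradation of proteins from the endoplasmic reticulum, had a mean of 1.20 ± 0.24 (SD, n = 4). The member below 0 was Chac1, a glutathione-degrading enzyme of the unfolded protein response, at -0.70; it was named after its value was seen. Hsph1 was above 2 in mice 1 and 2 and near 0.9 in mice 3 and 4. The list passed camera (adjusted p = 0.00233), but not at adjusted p = 0.602 with an estimated correlation. Of 28 proteasome genes, 2 passed above 0 and 0 below, with the same counts when adjusted over the list alone: Psmd2 at 0.53 ± 0.13 and Psmb2 at 0.39 ± 0.08 (SD, n = 4). The proteasome list, with a median of 0.17, did not pass camera (adjusted p = 0.296); its medians were -0.07, -0.08, 0.49 and 0.28 in mice 1 to 4. Hsph1 and Psmb2 were lost whichever mouse was left out and Psmd2 without mouse 1, 3 or 4, at limma adjusted p up to 0.0905.

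Of 31 tested endothelial markers, 10 passed above 0 and 0 below, 12 and 1 when adjusted over the list alone, with a median of 0.34 and a positive median in each mouse. Beside Tmem100, the sphingosine-1-phosphate receptor gene S1pr1 had a mean of 1.03 ± 0.18, the angiopoietin receptor gene Tek of 1.18 ± 0.24 and the adhesion molecule gene Pecam1 of 1.07 ± 0.42 (SD, n = 4). Cav1, a gene of caveolae, had a mean of 0.91 ± 0.18 (SD, n = 3). The list passed camera (adjusted p = 0.00233), but not at adjusted p = 0.602 with an estimated correlation. Pecam1 was lost without mouse 4 (limma adjusted p = 0.0652).

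No list of lung epithelium passed camera with all 4 mice. Of 19 genes of alveolar type II cells, which make surfactant, 1 passed above 0 and 0 below, the same when adjusted over the list alone. This was the surfactant protein gene Sftpa1, at 1.28 ± 0.26 (SD, n = 4). The surfactant genes Sftpc (0.46 ± 0.82, SD, n = 3; limma adjusted p = 0.378) and Sftpd (0.19 ± 0.43, SD, n = 4; limma adjusted p = 0.464) did not pass. The list median was 0.23 and camera gave an adjusted p of 0.0554, which fell under the threshold without mouse 3 (0.0434) or mouse 4 (0.0199). Of 21 genes of the flat alveolar type I cells, 4 passed above and 1 below 0, 5 and 2 when adjusted over the list alone, with a median of 0.01 (camera adjusted p = 0.939). These were Sema3e at 1.11, Rtkn2 at 1.19, Cyp2b10 at 0.89 and Limch1 at 0.39, and, below 0, the water channel gene Aqp5 at -0.34. Ager, a type I cell receptor gene, had a mean of 1.16 ± 0.77 (SD, n = 4) and did not pass (limma adjusted p = 0.0521). Aqp5 and Limch1 were lost whichever mouse was left out, Cyp2b10 without mouse 1, 2 or 3 and Rtkn2 without mouse 4, at limma adjusted p up to 0.158. Limch1 has no value in mouse 4, and its own values were the same in the fit without that mouse.

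Of 20 club cell genes, 2 passed above and 1 below 0, 3 and 1 when adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.387). Fmo2 and the carbonyl reductase gene Cbr2 (1.17 ± 0.70, SD, n = 4) lay above 0 and Reg3g below it. The club cell secretory gene Scgb1a1 did not pass (-0.15 ± 0.69, SD, n = 4; limma adjusted p = 0.727), being above 0 in mice 1 and 2 and below it in mice 3 and 4. Of 15 ciliated cell genes, 1 passed below 0 and 0 above, the same when adjusted over the list alone: the adenylate kinase gene Ak1 at -1.41 ± 0.46 (SD, n = 4). Ak1 is also abundant in skeletal muscle, and the list did not pass camera (median -0.05, adjusted p = 0.453). Of 26 genes of xenobiotic metabolism, 5 passed above 0 and 0 below, 6 and 0 when adjusted over the list alone, with a median of 0.11 (adjusted p = 0.441 by camera on the 23 with 4 values and 0.0166 by cameraPR on all 26). They were Fmo1, Fmo2, Cbr2, Cyp2b10 and the acetyltransferase gene Nat2 at 0.64 ± 0.18 (SD, n = 3). Cbr2 and Nat2 were lost without mouse 1, 3 or 4, Cyp2b10 without mouse 1, 2 or 3 and Fmo1 without mouse 4, at limma adjusted p up to 0.119.

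Immune genes passed on both sides of 0, and no immune list passed camera with all 4 mice and centred arrays. Of 9 neutrophil genes, 2 passed below 0 and 0 above, 3 and 2 when adjusted over the list alone; both were calprotectin genes, S100a8 and S100a9, and the list median was -0.16 (camera adjusted p = 0.242). Of 22 macrophage genes, 2 passed above 0 and 1 below, 3 and 3 when adjusted over the list alone. These were the mannose receptor gene Mrc1 at 0.74 ± 0.16 (SD, n = 3), the apolipoprotein gene Apoe at 0.96 ± 0.51 and the lipid droplet gene Plin2 at -0.82 ± 0.44 (SD, n = 4). The macrophage median was -0.20 (camera adjusted p = 0.112, and 0.00591 without mouse 4, whose own median was 0.11). Of 38 chemokine and cytokine genes, 2 passed above 0 and 6 below, 3 and 6 when adjusted over the list alone, with a median of -0.17. Cxcl12 had a mean of 1.03 ± 0.40 and Cxcl11 of 0.40 ± 0.09, whereas Cxcl14 had -0.90 ± 0.18, Mif -1.08 ± 0.33 and Ccl5 -0.66 ± 0.38 (SD, n = 4). The list gave a camera adjusted p of 0.0551, or 0.0157 without mouse 3, 0.0134 without mouse 4 and 0.0426 without centring. By cameraPR on all 38 genes, against 27 with 4 values in camera, it was 0.0473; both the test and the genes differ there. Il6, a cytokine gene of acute inflammation, did not pass (-0.50 ± 0.57, SD, n = 4; limma adjusted p = 0.169). S100a8, Cxcl14 and Mif passed limma whichever mouse was left out. Ccl5 was lost in every such fit, Apoe and Cxcl11 without mouse 1, 3 or 4, Plin2 without mouse 1, 2 or 3, Mrc1 and Cxcl12 without mouse 3 or 4 and S100a9 without mouse 4, at adjusted p up to 0.121.

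Of 34 interferon response genes, 3 passed above and 1 below 0, 4 and 1 when adjusted over the list alone. Irf1, an interferon-induced transcription factor gene, had a mean of 0.59 ± 0.06, Ube2l6 of 0.57 ± 0.23, Tgtp1 of 0.56 ± 0.34 and Zbp1, a nucleic acid sensor gene, of -0.93 ± 0.54 (SD, n = 4). The median of this list was -0.12, with -0.21, -0.29, 0.25 and 0.12 in mice 1 to 4, while camera, on the 23 genes with 4 values, placed it above 0 without passing (adjusted p = 0.847). Among 18 genes of T and NK cells (median -0.10), Cd2 passed at 0.47 and Ccl5 below 0, and among 12 genes of B and plasma cells (median -0.09), Blnk passed at -0.46; the counts were the same when adjusted over the list alone. Of 7 mast cell and eosinophil genes, Kit at 0.67 and Siglecf at 0.54 passed, 2 above and 1 below 0 when adjusted over the list alone, although the list median was -0.16 and its mean 0.005. Their camera adjusted p values were 0.417, 0.342 and 0.697. Of 12 complement genes (median -0.17, camera adjusted p = 0.136) and 20 antigen presentation genes (median 0.15, camera adjusted p = 0.387, 0.0481 without mouse 2), 0 passed, also when adjusted over the list alone. Of 19 genes of the acute phase and coagulation (median 0.00425, mean -0.06, camera adjusted p = 0.987), the thrombomodulin gene Thbd passed at 0.55 and F13a1, a clotting factor subunit gene, at -0.58, the same when adjusted over the list alone. Of the 11 genes named here, Irf1 alone passed limma whichever mouse was left out. Ube2l6, Ccl5, Blnk and Thbd were lost in every such fit, Zbp1, Tgtp1, Cd2 and F13a1 without mouse 1, 3 or 4, Siglecf without mouse 3 or 4 and Kit without mouse 3, at adjusted p up to 0.148.

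Genes of the extracellular matrix also lay on both sides of 0. Of 48 tested members, 4 passed above and 3 below 0, 5 and 3 when adjusted over the list alone, with a median of 0.06 (camera adjusted p = 0.629). Serpinh1, a collagen chaperone gene, had a mean of 0.97 ± 0.20, the matricellular gene Postn of 0.86 ± 0.26 and the collagen hydroxylase gene P4ha2 of 0.70 ± 0.26, while Col15a1, a basement membrane collagen gene, had -0.88 ± 0.17 (SD, n = 4). The fibrillar collagen genes Col1a1 and Col3a1 did not pass, and Col1a2 had too few values. Col1a1 had a mean of 0.23 ± 0.32 (SD, n = 4, limma adjusted p = 0.279) and Col3a1 of -0.55 ± 0.74 (SD, n = 4, limma adjusted p = 0.219). Col3a1 was -1.02 and -1.35 in mice 1 and 2 and 0.07 and 0.09 in mice 3 and 4. Tnc (-0.04), Eln (0.06), the matricellular gene Ccn2 (0.25) and the growth factor gene Tgfb1 (0.21) did not pass either. P4ha2 was lost without mouse 3 or 4, at limma adjusted p up to 0.0627.

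Of 22 genes of matrix proteases and their inhibitors, 3 passed above and 1 below 0, 4 and 1 when adjusted over the list alone. Timp3, a protease inhibitor gene, had a mean of 0.71 ± 0.14, Mmp3 of 0.54 ± 0.25 and Adam9 of 0.52 ± 0.28 (SD, n = 4), and Mmp14 of -0.39 ± 0.03 (SD, n = 3). The list median was 0.17 and camera gave an adjusted p of 0.0554, or 0.0432 without mouse 2. Of 21 fibroblast genes, 3 passed above and 1 below 0, 6 and 3 when adjusted over the list alone, with a median of 0.07 (camera adjusted p = 0.847). They were Inmt, Dpep1 at 0.84, Limch1 at 0.39 and Pi16 at -0.48. Of 17 genes of smooth muscle and myofibroblasts, 1 passed above 0 and 0 below, the same when adjusted over the list alone: the cadherin gene Cdh11 at 0.83 ± 0.22 (SD, n = 4). That list had a median of -0.04 and a mean of 0.03 (camera adjusted p = 0.939). Timp3, Inmt and Cdh11 passed limma whichever mouse was left out. Mmp14, Adam9, Pi16 and Limch1 were lost in every such fit, Mmp3 without mouse 1, 3 or 4 and Dpep1 without mouse 1, at adjusted p up to 0.158. Mmp14 has no value in mouse 1 and Limch1 none in mouse 4, and their own values were the same in the fits without those mice.

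Of 20 target genes of p53, the transcription factor activated by DNA damage, 1 passed above and 3 below 0, the same when adjusted over the list alone. Cdkn1a, which encodes the cell cycle inhibitor p21, had a mean of -0.86 ± 0.24 (SD, n = 4; limma adjusted p = 0.0121), and the cyclin G1 gene Ccng1 of -1.46 ± 0.81 (SD, n = 4). Ei24 lay at -0.43 and the antiproliferative gene Btg2 at 0.52. Mdm2, which encodes the ubiquitin ligase of p53, did not pass (-0.36 ± 0.81, SD, n = 4; limma adjusted p = 0.451). The list median was -0.04 (camera adjusted p = 0.422). Of 28 DNA repair genes, 3 passed above and 2 below 0, 3 and 4 when adjusted over the list alone: the cohesin gene Rad21 at 0.65, Parp2 at 0.38, Ogg1 at -0.55, Rpa1 at -0.40 and Ercc3 at 0.26, the last named after its value was seen. Their median was 0.02 while camera placed the list below 0 without passing (adjusted p = 0.697). Of the genes in the fixed rule, Cdkn1a passed limma whichever mouse was left out. Ei24, Parp2, Ogg1 and Rpa1 were lost in every such fit, Btg2 without mouse 1, 3 or 4, Ccng1 without mouse 1, 2 or 3 and Rad21 without mouse 4, at adjusted p up to 0.106.

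Of 36 tested cell cycle genes, 1 passed above and 2 below 0, 1 and 1 when adjusted over the list alone, and the medians were -0.31, -0.40, 0.02 and -0.04 in mice 1 to 4. Hmgb2 lay at 0.54 ± 0.18, Racgap1, which acts in cell division, at -0.53 ± 0.22 and the mitotic kinesin gene Kif2c at -0.32 ± 0.13 (SD, n = 4). The proliferation marker gene Mki67 did not pass (-0.53 ± 0.42, SD, n = 4; limma adjusted p = 0.0884). The list passed camera (adjusted p = 0.0375), but not without mouse 1 (0.0889) or mouse 2 (0.286), nor at adjusted p = 0.845 with an estimated correlation. By fry the cell cycle list did not pass either (adjusted p = 0.399). Hmgb2 and Racgap1 were lost without mouse 1, 3 or 4 and Kif2c whichever mouse was left out, at limma adjusted p up to 0.137.

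Of 28 genes of oxidative stress and metallothioneins, 1 passed above and 4 below 0, 2 and 6 when adjusted over the list alone, with a median of -0.01 (camera adjusted p = 0.296). Beside Mt2, the peroxiredoxin gene Prdx1 had a mean of -1.12 ± 0.43, the thioredoxin reductase gene Txnrd1 of -0.59 ± 0.16 and Blvrb of -0.36 ± 0.13 (SD, n = 4). Gclm, a subunit of the enzyme that starts glutathione synthesis, had a mean of 0.59 ± 0.13 (SD, n = 3). Of 20 genes of fatty acid and cholesterol synthesis, 1 passed above 0 and 0 below, the same when adjusted over the list alone: the desaturase gene Scd2 at 1.21 ± 0.27 (SD, n = 4). That list had a median of 0.04 (camera adjusted p = 0.690). Of 11 red blood cell genes, the heme synthesis gene Alas2 at 0.53 and the blood group gene Rhd at -0.98 passed, 2 above and 1 below 0 when adjusted over the list alone, with a median of 0.00425 and a mean of -0.04 (camera adjusted p = 0.847). Of 5 genes of peribronchial lymph and nerve, 0 passed, also when adjusted over the list alone (median -0.09, camera adjusted p = 0.586). Scd2 passed limma whichever mouse was left out. Blvrb and Alas2 were lost in every such fit, Mt2 without mouse 1, 3 or 4, Gclm without mouse 1, 2 or 4, Rhd without mouse 1, 2 or 3, Txnrd1 without mouse 1 or 3 and Prdx1 without mouse 4, at adjusted p up to 0.139; Mt2 has no value in mouse 1.

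**Figure D3:**
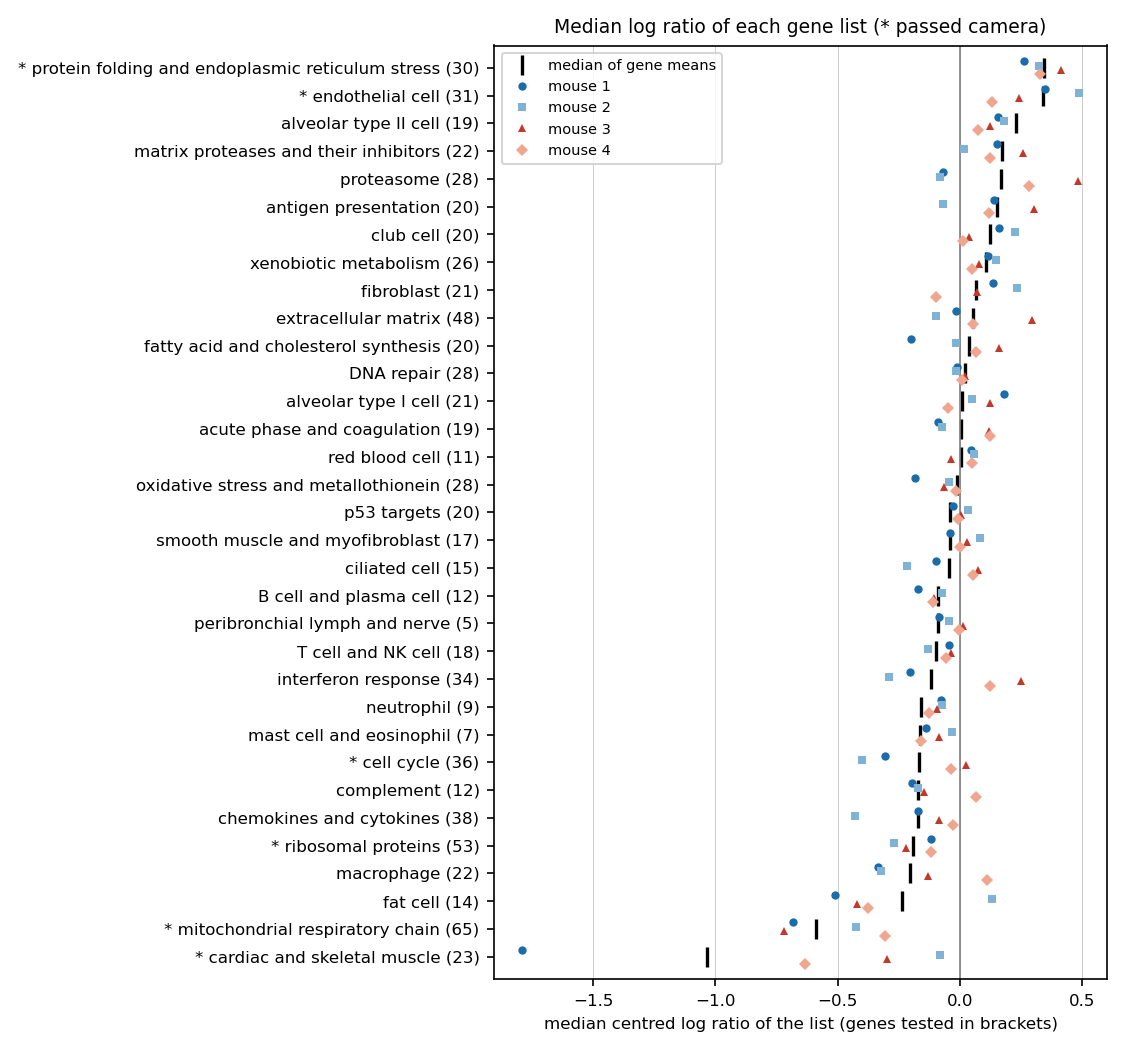
Median centred log ratio (horizontal axis, base taken as 2) of each of the 33 gene lists, with the number of genes tested in brackets. Symbols are the medians in single mice, black ticks are the medians of the gene means, and asterisks mark the 6 lists that passed camera with its preset correlation. The respiratory chain list lies between -0.31 and -0.72 in the 4 mice, and the muscle list between -0.08 and -1.79.

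The 4 arrays correlated positively with each other across spots, which are not independent replicates. Pearson's r was 0.858 (Spearman's rho 0.792) between mice 3 and 4 and 0.728 (0.683) between mice 1 and 2. In the remaining pairs r was 0.537 for mice 1 and 3, 0.574 for mice 1 and 4, 0.453 for mice 2 and 3 and 0.468 for mice 2 and 4, with rho from 0.414 to 0.491. The arrays thus ran in the same orientation as far as the values show. All share the pool, whose own deviations add a positive correlation that cannot be separated with 1 pool. Col3a1, Tnc, Mdm2 and Sftpd were below 0 in mice 1 and 2 and above it in mice 3 and 4, Scgb1a1 had the opposite signs, and none of these 5 genes passed the test. Of the lists, the medians of proteasome, ciliated cell, matrix, lipid synthesis, DNA repair, interferon and acute phase genes were below 0 in mice 1 and 2 and above it in mice 3 and 4, and none of these lists passed camera with all 4 mice. Over 1 mean per pair of similar arrays, 0 of the 99 named genes past the test passed limma (lowest adjusted p = 0.113). That setting has few degrees of freedom, with 2 means. With the pairs as a random block, a setting that rests on 1 correlation estimated from only 2 pairs, 58 of the 99 genes passed limma. Lost there, at adjusted p up to 0.102, were Cidea, Hrc, Cox7a1, Cox8b, Nppb, Mt2, Ldb3, Gpd1, Plin4, Adipoq, Psmb2, Limch1, Aqp5, Cbr2, Apoe, Plin2, Cxcl11, Ccl5, Ube2l6, Zbp1, Tgtp1, Cd2, Blnk, F13a1, Thbd, Mmp3, Mmp14, Adam9, Pi16, Btg2, Ccng1, Ei24, Parp2, Ogg1, Rpa1, Hmgb2, Racgap1, Kif2c, Gclm, Blvrb and Rhd.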

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

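No test in this part was chosen after a result was seen: every named gene with 4 values and every gene list was checked for a mouse that stood apart from the other 3 by Dixon's rule. Of 130 such groups, 97 genes and 33 lists, 7 stood out, and chance gives about 6.5 (1 in 20) for independent arrays. The arrays of mice 1 and 2, and of mice 3 and 4, resembled each other, which changes how often 1 mouse stands apart, so this number is only a rough guide.

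Rpl39 was -0.69 in mouse 4 and between -1.14 and -1.21 in the other mice. Cyp2b10 was 0.40 in mouse 4 and between 0.98 and 1.09 in the others. Ube2l6 was 0.91 in mouse 3, against 0.44 to 0.50. F13a1 was -0.17 in mouse 2, against -0.69 to -0.75. Pi16 was -0.76 in mouse 3, against -0.37 to -0.43. Rpa1 was -0.68 in mouse 2, against -0.29 to -0.32. The median of the red blood cell list was -0.037 in mouse 3 and between 0.05 and 0.06 in the others.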

How the results depend on the processing

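The removal of the trend with genomic span and of muscle and fat genes, and the settings with pairs of similar arrays, were chosen after seeing the data; all other alternatives were fixed before. No paired analysis was possible because the arrays form 1 group. The genes that passed, 1048, numbered between 1002 and 1185 without centring, with equal spread or with other limits on missing values. They did so too with a robust prior, array weights, 1 probe per gene, no span trend or no muscle and fat genes. Of those tested, 0 changed sign in the settings where this was counted, all of these but the last 3. With values on all 4 arrays, 936 of the 1048 were tested. Only no centring and equal spread could have changed a sign. The other settings where signs were counted keep each gene's mean or only weight values of 1 sign. With the pairs of similar arrays as a random block 402 genes and 565 probes passed, and over 1 mean per pair 0 and 0 by limma (1566 and 1874 at an unadjusted p under 0.05); 2 means leave few degrees of freedom. An adjusted p of 0.01 left 103 genes and 168 probes, and a 1.5-fold minimum 540 and 676, as fewer can pass a stricter limit. Leaving out a mouse gave 296 to 573 genes, 448 to 662 probes, 41 to 58 genes over 2-fold and 5 to 9 lists called. Over 1.5-fold on every array, 159 genes were counted. For lists, the setting with an estimated correlation could hardly call any with 4 arrays. With an estimated correlation 0 of 33 lists were called, fry called 9 and cameraPR, run on all genes with at least 3 values, 8; by fry the respiratory chain and ribosomal lists (both 0.0506), muscle (0.128) and cell cycle (0.399) missed the threshold, while neutrophil (0.00346), club cell and xenobiotic (both 0.0106), oxidative stress (0.0116), matrix protease (0.0310), B cell (0.0374) and alveolar type II (0.0435) lists passed. By cameraPR on these genes xenobiotic (0.0166; 26 genes against 23) and chemokine (0.0473; 38 against 27) lists passed in addition, also with the pairs as a block (8 lists; 0.0119 and 0.0324), and test and genes were not separated, and without centring the chemokine list did (0.0426).

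Of 1113 refits of named genes under the other alternatives, 948 kept their side of 0 and of the threshold, 161 lost it and 4 gained it (Ager). Of 452 without a mouse, 266 kept both, 179 lost the threshold, 1 gained it and 6 changed sign, all of genes that had not passed; their ranges were -0.0265 to 0.14 for Eln, -0.55 to 0.32 for Myh6, -0.43 to 0.0677 for Scgb1a1 and -0.20 to 0.14 for Tnc. Named genes past the test had the same sign on every array, so leaving out a mouse could not turn theirs. Lists changed side only where they passed neither way. Their adjusted p by fry was 0.0506 for mast cells, 0.582 for red blood cells and 0.497 for smooth muscle, and by cameraPR 0.780 for acute phase, 0.788 for interferon, 0.898 for mast cells, 0.810 for red blood cells and 0.7998 for smooth muscle. By cameraPR with the block it was 0.745 for acute phase, interferon and smooth muscle, 0.892 for mast cells and 0.821 for red blood cells. Smooth muscle had 0.714 without muscle and fat genes. Without a mouse it was 0.760 to 0.947 for acute phase, 0.560 to 0.947 for alveolar type I, 0.378 to 0.760 for matrix, 0.419 to 0.857 for fibroblasts, 0.361 to 0.8285 for interferon, 0.603 to 0.935 for red blood cells and 0.780 to 0.947 for smooth muscle. The cause of these changes was not tested. Limits from signal over background could not be examined, since the table has ratios only.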

Other observations

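Except for the comparison of large and small subunits, the tests in this part were chosen after the result was seen, and for that one some subunit values had been seen too. Among 26 gene families formed from shared symbols, 0 passed camera after adjustment. The zinc finger genes (Zfp), with 8 of 91 past the test above 0 and 0 below, came closest (median 0.09, adjusted p = 0.107), followed by the mitochondrial ribosomal proteins (Mrpl and Mrps), with 3 above and 5 below (median -0.12, adjusted p = 0.219). Their camera p values were 0.00410 and 0.0168 before adjustment.

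Of the genes measured, 10 have 17 probes each, which shows how far probes of 1 gene differ. The 13 probes of Hspa1a with at least 3 values had means from 1.74 to 3.66, the 17 of the translation factor gene Eif4a2 from 0.76 to 1.23, and the 17 of Cyc1, a respiratory chain gene, from -0.77 to -0.21. The 14 probes of the glycolytic gene Gapdh ranged from 0.06 to 0.72. Probe means lay on both sides of 0 for Ldha (-0.44 to 0.09), Nup62 (-0.12 to 0.59) and Rpl5 (-0.17 to 0.37). For Tcea1, Tcf3 and Top1 all were above 0. This group of genes was looked at after its values were seen.

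The respiratory chain list below 0 may have a technical source. A trend of the log ratio with genomic span is argued against, since the list median stayed at -0.554 (quartiles -0.921 and -0.201) after the trend was removed. Muscle or fat tissue in some samples is argued against as the whole cause, since 30 enzymes of the citric acid cycle and fatty acid oxidation, abundant in the same mitochondria, had a median of 0.041 (quartiles -0.228 and 0.206). Short transcripts lying lower would fit: 6 large subunits had a median of -0.142 against -0.616 for the other 59. A permutation test of the difference in means gave p = 0.0445. It took the genes as independent, although the correlation within the list was estimated at 0.269. Transcript lengths were not available here, and 6 genes are few. An effect of the treatment stays open and untested.

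Genes of bleomycin injury lay on both sides of 0, which leaves the direction of the ratio open. One explanation, that the deposited ratio is the control pool over the treated mouse, predicts that the called members of the matrix, p53 and macrophage lists, fixed beforehand to be set beside the direction, lie mostly below 0. Of 14 such members, 7 were below 0 and 7 above (exact binomial p = 1), so that the 2 directions cannot be told apart by these lists.

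The arrays of mice 1 and 2 were alike, and those of mice 3 and 4, for a reason that is not known: the smaller of the 2 correlations, 0.728, was above the largest of the 4 others, 0.574, by 0.155. The genes of the muscle and fat lists are unlikely as the source by themselves, since without them the difference was 0.170. Their removal moved the 2 correlations only to 0.725 and 0.555. Other genes of muscle or fat tissue were kept, so such tissue stays open as a source. The position of the spot in the table stays open: subtracting a running median over neighbouring spots left the difference at 0.155, but it also moved neither correlation and so tested nothing. Slides, dyes, dates of the experiments and differences between the mice in injury stay open and untested, and none is recorded in the sources used here.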
